A study of Tupaia belangeri chinensis with 12 samples.

How the data were processed

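Poly(A)-selected RNA was sequenced from laser-captured layers of the fetal cortex of the Chinese tree shrew. The 12 libraries comprise 3 each of the ventricular zone (VZ), the inner subventricular zone (ISVZ), the outer subventricular zone (OSVZ) and the cortical plate (CP). The labels give embryonic day 37 for every library, while the names of the deposited tables carry day 35; the labels were followed. Nothing in the labels says that the 3 libraries of a layer came from separate animals, so p-values measure the spread between these samples, which may be technical.

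The authors deposited 1 table per library of gene-level FPKM with lower and upper bounds, in the layout that Cufflinks writes, per the file headers. HISAT2 and Cufflinks are named in the submitters' processing notes. Their versions, the genome build, the annotation and the use of strand are not given in the sources used here, so coordinates are those of the deposited tables. Each table holds 81792 entries for 81418 gene IDs, and gene symbols were taken from the tables themselves, which carry 26568 symbols. Entries that share an ID (360 IDs) were summed. The 4 IDs with a failed status in any library were left out.

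FPKM is already normalised for gene length and depth, and no read counts were used here. Each library was further scaled by 1 factor, the median of its ratios to the geometric mean profile over the 10202 genes at 1 FPKM or more in all libraries, and the factors ranged from 0.946 to 1.06. Levels are given as scaled FPKM, mean ± SD over 3 libraries. Genes at 1 or more in at least 3 libraries were tested, which kept 14109, of which 12399 carry numbered gene IDs of the annotation, 1160 are antisense and 529 are intergenic noncoding. Antisense genes, genes that overlap another, and genes named as a copy (1835 tested names end in a copy number, such as UBE2Cli1) are uncertain, since reads could have been divided between them.

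Read depth could not be read from FPKM. A relative depth was computed from the width of the deposited bounds, and it ranged from 0.668 in VZ 1 to 1.81 in OSVZ 3. The median half-width of the bounds over expressed genes was 7.80% to 12.8% of the value.

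Differences were tested with limma 3.58.1 in R 4.3.3 (linear model over the 4 layers, empirical Bayes with an intensity trend, 8 residual degrees of freedom) on log2 of scaled FPKM plus 1. The tests were a moderated F test over the 4 layers, CP minus the mean of VZ, ISVZ and OSVZ, OSVZ minus VZ, ISVZ minus VZ, and OSVZ minus ISVZ. Adjusted p-values are Benjamini-Hochberg over the 14109 genes, with a threshold of 0.05, and all tests are two-sided. Log2 differences are given ± SE of the model. CCNB1IP1, the gene in the title of the series, lies below the filter and was tested with an exact permutation test of its F statistic over all 369600 assignments of the libraries to the layers.

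Before the data were examined, 26 gene lists were fixed, with 368 distinct genes, of which 339 were found by symbol and 277 were tested. They cover radial glia, outer radial glia, intermediate progenitors, newborn and migrating, upper-layer, deep-layer and subplate neurons, Cajal-Retzius cells, synapse and axon growth, G1/S and G2/M genes, Notch signalling, extracellular matrix and integrins, cortical folding and malformation genes, interneurons, oligodendrocyte precursors, astrocytes, microglia, endothelium and mural cells, erythroid cells, meninges, choroid plexus, ependymal and motile cilia, subpallial progenitors, stress and immediate early genes, and mitochondrial transcripts. The Cajal-Retzius, erythroid and mitochondrial lists had fewer than 3 tested members and were not tested as lists. The other 23 lists were tested in the 4 contrasts with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 92 tests. Of these, 50 passed at the preset correlation and 0 passed with a correlation estimated from the residuals, where the smallest adjusted p was 0.183. Limma's fry was also run on the 92 tests. It asks whether a list's members differ at all, not whether they differ more than other genes. Its adjusted p in CP was 7.43e-07 for radial glia, 1.495e-05 for folding genes and 0.335 for newborn and migrating neurons. Below, lists are said to pass or not by camera at the preset correlation. Members past the threshold are counted over all genes and adjusted over the list alone.

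The genes named were chosen by a rule fixed before the data were examined. In each contrast it takes the 10 largest and the 10 smallest log2 differences among genes with a symbol that passed the test and whose libraries on the 2 sides do not overlap. It adds up to 4 passing and 2 other members of each list, CCNB1IP1, and PAX6, HOPX, EOMES, TBR1 and MKI67 as layer checks; 1 further gene of the rule is not reported here. Members that went against the rest of their list are also named; they lie outside the rule, and their calls were not run through the alternatives. Other names outside the rule are said to be chosen after their values were seen. Of 70 genes named by size, 31 overlap another annotated gene with a symbol, and those in the text were mostly taken from the others. Exceptions in the text include GABRA5, TTR, FOLR1, SOX2 and TBR1.

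The testing step was checked on simulated data with independent normal noise for the 14109 genes. Changes were added only to genes above a set mean level, 66 or 67 genes per size. Recovery for genes nearer the filter was not measured. For OSVZ against VZ it recovered 65.7% of genes changed by 1 log2 unit and 95.5% of those changed by 2. For ISVZ against VZ it recovered 77.6% and 95.5%, for OSVZ against ISVZ 71.6% and 93.9%, for CP against the germinal layers 80.6% and 92.4%, and for the F test 76.1% and 95.5%. At a change of 0.5 it recovered 19.4%, 32.8%, 17.9%, 35.8% and 13.4% in the same order, and it called 3, 7, 6, 7 and 8 unchanged genes.

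Alternatives were the FPKM as deposited, totals set equal, quantile normalisation, a pseudocount of 0.1, no filter, a filter of 5, no intensity trend, robust estimation, the replicate number as a block, fits of the compared libraries alone, and each library left out in turn. A fit without the VZ libraries with the highest TTR, VZ 1 and VZ 2, was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.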

Results

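Gene expression was measured in 4 layers of the fetal cortex of the Chinese tree shrew, a small mammal closely related to primates. The layers were the VZ, which lines the ventricle and holds radial glia, the ISVZ and OSVZ above it, and the CP, where neurons settle. Each layer has 3 libraries, named here VZ 1 to CP 3. Summed FPKM per library ranged from 244696 in OSVZ 1 to 276661 in VZ 2, and 12278 to 13267 genes reached 1 FPKM. No pair of libraries held identical values (0 pairs), and the highest Pearson r between 2 libraries across genes was 0.974.

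The layers lined up in their anatomical order on the first principal component, which held 61.0% of the variance. Profiles were closest between neighbours, with a mean r across genes of 0.940 for VZ and ISVZ and 0.948 for ISVZ and OSVZ. The mean r was 0.899 for VZ and OSVZ, 0.904 for OSVZ and CP, and 0.780 for VZ and CP. Libraries of the same layer had a mean r of 0.959 to 0.968. These are correlations across genes, which are not independent replicates. The limma F test called 7304 of 14109 genes (51.8%) different among the layers.

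**Figure D1:**
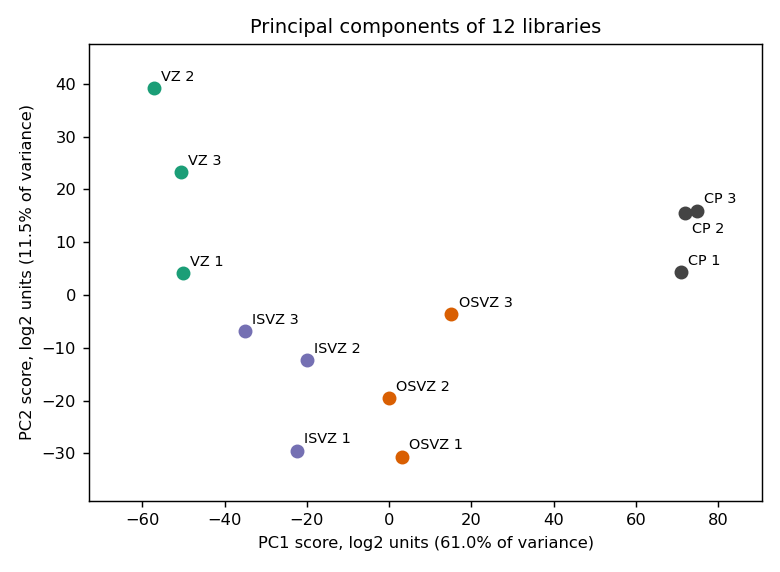
Scores of the 12 libraries on the first 2 principal components of log2 of scaled FPKM plus 1 (61.0% and 11.5% of the variance), 1 point per library, coloured by layer. Along the first component the libraries run from VZ through ISVZ and OSVZ to CP, with no overlap between layers.

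Genes that mark the cell types of each layer were read first. PAX6, a transcription factor of radial glia, was at 28.6 ± 7.46 scaled FPKM in VZ (SD, n = 3), 19.6 ± 7.43 in ISVZ, 15.5 ± 2.77 in OSVZ and 0.434 ± 0.295 in CP. EOMES, which marks intermediate progenitors, was at 57.3 ± 13.5, 54.4 ± 21.5, 44.2 ± 9.52 and 0.232 ± 0.123 in the same order. MKI67, a gene of dividing cells, was at 37.0 ± 8.48, 32.4 ± 11.1, 19.2 ± 7.69 and 0.456 ± 0.205. TBR1, a gene of early-born projection neurons, was at 7.23 ± 3.82, 16.6 ± 1.83, 27.3 ± 2.25 and 26.9 ± 9.22. Its annotated gene spans 263382 bases and overlaps 4 other genes with a symbol, the highest at a mean of 39.6. The level of TBR1 is therefore uncertain. HOPX, used as a marker of outer radial glia in other species, was highest in VZ at 3.53 ± 0.302, with 1.52 ± 1.21 in ISVZ, 0.797 ± 0.408 in OSVZ and 0.182 ± 0.160 in CP.

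**Figure D2:**
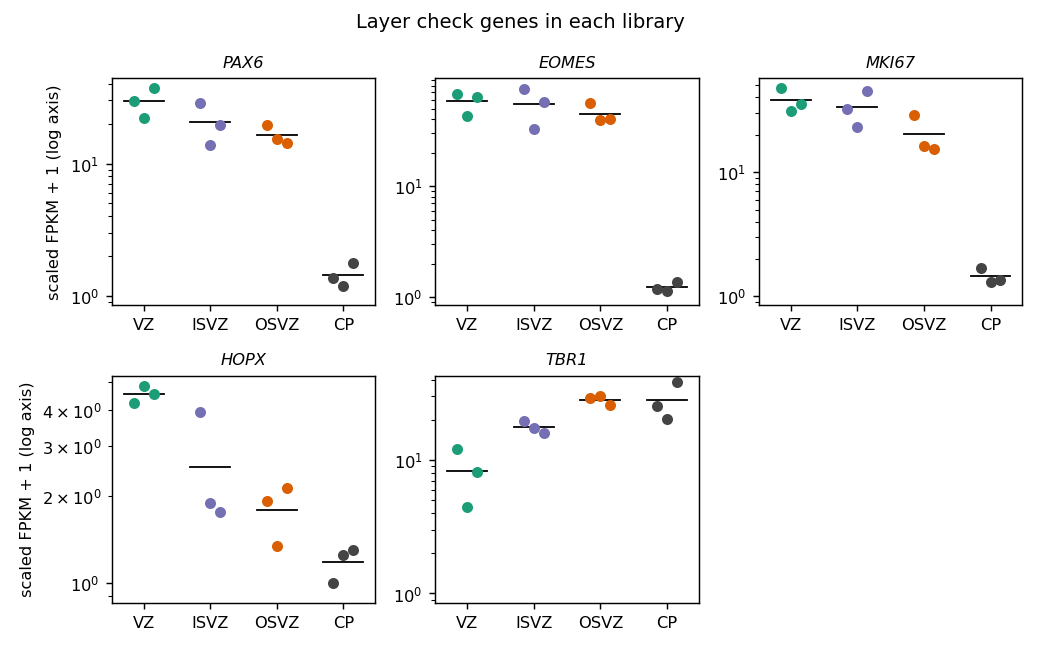
Scaled FPKM plus 1 on a log axis for 5 layer check genes, 1 point per library and a line at the mean of each layer. EOMES and MKI67 are at 0.232 and 0.456 on average in CP, and TBR1 is at 26.9 there. The annotated TBR1 gene overlaps 4 other genes with a symbol.

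The title of the series concerns CCNB1IP1, which encodes a RING finger protein known from meiotic recombination and from the control of cyclin B. Its annotated gene (TSDBGID.22407, chromosome 5, 107782925 to 107812804) was close to 0 in all 4 layers. Scaled FPKM was 0.0628, 0.117 and 0.0278 in VZ 1 to 3, 0.0751, 0.0217 and 0.0228 in ISVZ 1 to 3, 0.0443, 0 and 0.0605 in OSVZ 1 to 3, and 0.0184, 0.0985 and 0 in CP 1 to 3, so it is listed at 0 in 2 libraries. The deposited lower bound was 0 in every library, and the highest upper bound was 0.270 in VZ 2. No difference among the layers was detected, with an exact permutation p of 0.717 (n = 3 per layer). The annotation also lists genes known to be abundant in fetal cortex at or near 0, such as TUBA1A and FABP7 (listed at 0) and ASPM (at most 0.149 FPKM). CCNB1 is at most 0.584 while its annotated copy CCNB1li1 is at 39.9 ± 2.91 in VZ. Whether reads of CCNB1IP1, or of these other genes, were lost or assigned to a copy was not tested.

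**Figure D3:**
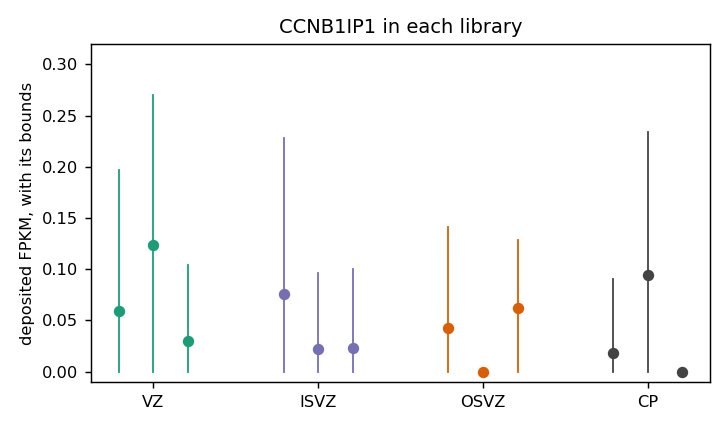
Deposited FPKM of CCNB1IP1 in each of the 12 libraries, with the deposited lower and upper bounds as vertical lines. All lower bounds are 0 and the highest upper bound is 0.270.

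CP was compared with the mean of the 3 germinal layers to describe the step from dividing progenitors to settled neurons. DYNC1I1, a neuronal dynein intermediate chain (TSDBGID.22849, chromosome 6, 100964038 to 101338314), was at 115 ± 14.3 in CP (SD, n = 3) and at 3.53 ± 1.45 in VZ, 3.57 ± 0.234 in ISVZ and 17.2 ± 2.86 in OSVZ. MEF2C, a transcription factor of maturing cortical neurons (TSDBGID.6173, chromosome 11, 86004952 to 86196714), was at 148 ± 14.0 in CP and at most 13.5 ± 6.47 on average elsewhere. In the other direction, EOMES (TSDBGID.18855, chromosome 29, 15848104 to 15861221) fell by 5.38 ± 0.227 log2 units (SE), and TOP2A, the topoisomerase of dividing cells (TSDBGID.9847, chromosome 16, 66577202 to 66611869), fell from 104 ± 8.27 in VZ to 1.02 ± 0.628 in CP. The limma contrast called 7435 genes, 3389 higher and 4046 lower in CP, and 1030 of the higher and 1208 of the lower genes differed at least 2-fold. The split depended on scaling, with 3628 higher and 3636 lower after quantile normalisation, 3280 and 4809 with equal totals, and 2904 and 4338 with the FPKM as deposited.

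Of 21 tested genes of synapse and axon growth, 19 were higher in CP, over all genes and adjusted over the list alone, among them SYT4, a synaptotagmin (log2 4.11 ± 0.54), GAP43, a growth cone protein (2.96 ± 0.32), and the microtubule protein MAPT (2.30 ± 0.18). GRIA1 (0.11 ± 0.15) and BSN (-0.03 ± 0.16) did not pass. The list passed camera at adjusted p = 5.80e-09, and adjusted p = 0.221 with an estimated correlation. Among upper-layer neuron genes 6 of 12 were higher and 2 lower, such as MEF2C (3.76 ± 0.27) and RORB (2.82 ± 0.19), while POU3F3 and LHX2 were lower. That list as a whole did not pass (adjusted p = 0.0807). Of 12 deep-layer genes 5 were higher and 2 lower (adjusted p = 0.291). Of 8 subplate genes 3 were higher and 2 lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.622). Of 14 genes of newborn and migrating neurons 5 were higher and 4 lower, or 7 and 5 adjusted over the list alone (adjusted p = 0.466).

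All 16 tested radial glia genes were lower in CP over all genes and adjusted over the list alone, with ID4, an inhibitor of differentiation, at log2 -4.11 ± 0.16, PAX6 at -3.89 ± 0.22 and SOX2 at -3.75 ± 0.18 (camera adjusted p = 7.13e-11, adjusted p = 0.183 with an estimated correlation). The cell cycle lists fell, with 15 of 15 G2/M genes lower, such as TOP2A (-5.25 ± 0.22), CCNB2 (-4.43 ± 0.19) and MKI67 (-4.30 ± 0.23), and 17 of 18 G1/S genes lower and SLBP higher, in each case also adjusted over the list alone. Camera gave adjusted p = 1.55e-11 and 1.49e-09, and adjusted p = 0.221 for both with an estimated correlation. Of 13 intermediate progenitor genes 9 were lower and TMEM158 higher, with NEUROD4 (-5.60 ± 0.31) and EOMES (-5.38 ± 0.23) the largest. Of 12 outer radial glia genes 10 were lower, such as the matrix protein TNC (-3.87 ± 0.19) and MOXD1 (-3.35 ± 0.23), and 2 were higher, the cytokine receptor IL6ST and the syndecan SDC3. Of 18 Notch pathway genes 15 were lower, such as MFNG (-3.77 ± 0.14) and NOTCH1 (-3.36 ± 0.16), while the ligand JAG2 and DTX4 were higher. Of 25 genes of the extracellular matrix and integrins 19 were lower, such as BCAN (-2.54 ± 0.28) and ITGA6 (-1.93 ± 0.21), and 0 higher. The counts adjusted over the list alone were the same for these 4 lists. Camera gave adjusted p = 4.61e-05, 7.73e-04, 6.40e-06 and 9.56e-06 in that order, and adjusted p = 0.183, 0.218, 0.221 and 0.232 with an estimated correlation.

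Genes of other cell types also differed between CP and the germinal layers. Microglia genes were lower in CP in 9 of 10 cases, among them the complement gene C1QB (-2.41 ± 0.16), as were 11 of 17 interneuron genes, such as SP9 (-3.02 ± 0.41; 12 adjusted over the list alone), 7 of 9 astrocyte genes (8 adjusted over the list alone), 7 of 11 genes of endothelium and mural cells, 7 of 7 subpallial progenitor genes and 6 of 6 genes of oligodendrocyte precursors. Camera gave adjusted p = 5.46e-04, 0.00318, 0.00199, 0.00629, 0.00524 and 0.0208 for these lists in that order, and adjusted p = 0.267, 0.493, 0.239, 0.357, 0.295 and 0.357 with an estimated correlation. Where not stated, the counts adjusted over the list alone were the same. The call for oligodendrocyte precursors was lost without CP 3 (adjusted p = 0.0504) and with a filter of 5 (0.0638). LUM, a proteoglycan of meningeal fibroblasts, was at 14.6 ± 2.15 in CP and at most 2.23 ± 1.99 on average elsewhere, but the meninges list did not pass (1 of 5 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.724).

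**Figure D4:**
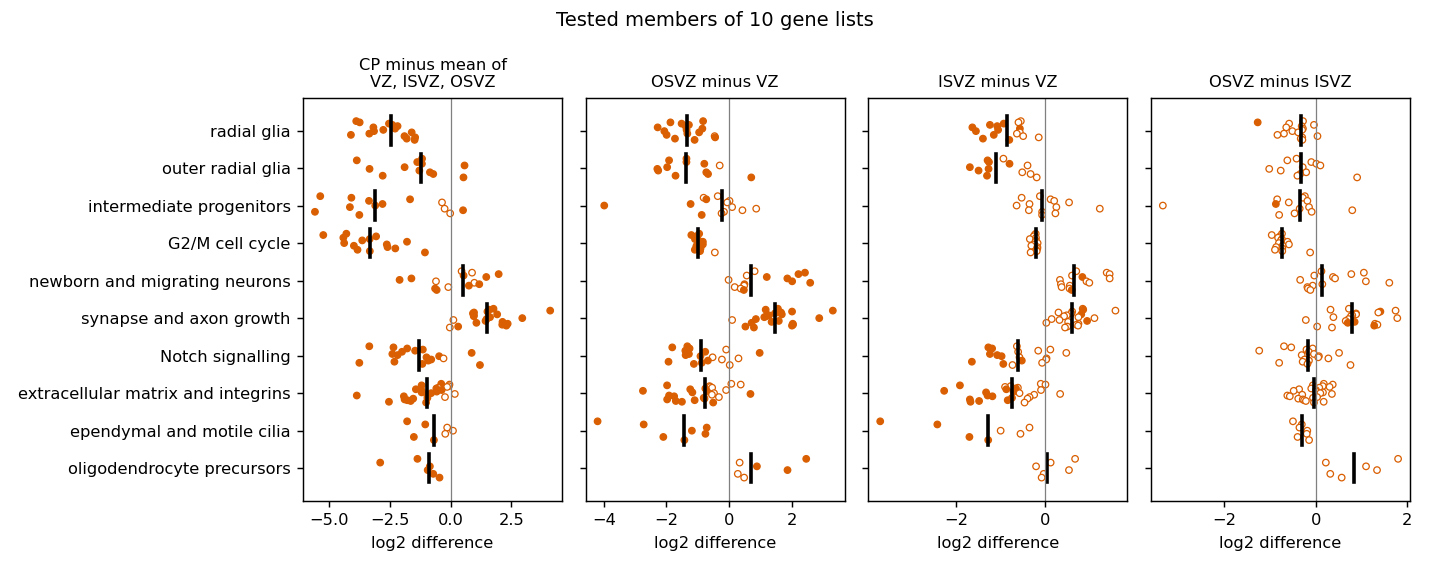
Log2 differences of the tested members of 10 gene lists in the 4 contrasts, 1 point per gene, filled where the adjusted p is under 0.05, with a bar at each list's median. In CP minus the germinal layers the medians are 1.52 for synapse and axon growth and -3.34 for G2/M genes.

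OSVZ was compared with VZ because the OSVZ is the progenitor layer linked to cortical expansion and folding. GAP43 (TSDBGID.4271, chromosome 1, 27385382 to 27502239) was at 128 ± 82.7 in OSVZ and 15.8 ± 8.92 in VZ (SD, n = 3), the cannabinoid receptor CNR1 (TSDBGID.20424, chromosome 4, 76872220 to 76901396) at 107 ± 18.4 against 16.2 ± 7.58, and BHLHE22, a transcription factor of projection neurons (TSDBGID.8547, chromosome 14, 74061572 to 74065559), at 96.9 ± 24.3 against 14.9 ± 7.51. GJA1, the gap junction protein of radial glia (TSDBGID.20944, chromosome 4, 45181726 to 45192198), was at 8.13 ± 3.26 in OSVZ and 82.4 ± 14.7 in VZ, and FOXJ1, the master regulator of motile cilia (TSDBGID.9691, chromosome 16, 48091653 to 48097894), at 0.236 ± 0.197 against 24.9 ± 16.6. The limma contrast called 3937 genes, 1652 higher and 2285 lower in OSVZ, and 567 and 760 of them differed at least 2-fold. After quantile normalisation the split was 2077 higher and 2084 lower.

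Of the 21 synapse and axon genes 20 were higher in OSVZ, over all genes and adjusted over the list alone, with GAP43 at log2 2.88 ± 0.39 and NEFM, a neurofilament, at 2.05 ± 0.28 (camera adjusted p = 8.26e-13, adjusted p = 0.183 with an estimated correlation). Of 14 genes of newborn and migrating neurons 8 were higher, or 10 adjusted over the list alone, among them NEUROD2 (2.43 ± 0.44), NEUROD6 (2.22 ± 0.50) and the guidance receptor NRP1 (2.02 ± 0.31), while DCX (0.57 ± 0.21) and ELAVL4 (0.18 ± 0.17) did not pass (1.88e-05, adjusted p = 0.221 with an estimated correlation). Of 12 upper-layer genes 4 were higher and 1 lower, also adjusted over the list alone, with PLXNA4, a semaphorin co-receptor, at 2.26 ± 0.35 (0.0282, adjusted p = 0.377 with an estimated correlation). That list's call was lost without VZ 2 (adjusted p = 0.0628), without OSVZ 1 (0.0748) and without OSVZ 2 (0.0615). It was also lost with quantile normalisation (0.0505), with a filter of 5 (0.0643) and without VZ 1 and VZ 2 together (0.0986, median 0.33 against 0.62). The median was 0.38 without OSVZ 1 and 0.93 without OSVZ 3. Among oligodendrocyte precursor genes 3 of 6 were higher, also adjusted over the list alone, with OLIG1 at 2.47 ± 0.38 and the receptor PDGFRA at 1.87 ± 0.31 (0.00524, adjusted p = 0.281 with an estimated correlation). Of 12 deep-layer genes 2 were higher and 1 lower (0.724), and of 8 subplate genes 3 were higher and 1 lower, or 6 and 1 adjusted over the list alone (0.0813).

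Radial glia genes were lower in OSVZ in 15 of 16 cases, over all genes and adjusted over the list alone, with VIM, an intermediate filament, at log2 -2.28 ± 0.22 and SLC1A3, a glutamate transporter, at -2.07 ± 0.28 (camera adjusted p = 1.49e-09, adjusted p = 0.183 with an estimated correlation). Genes described as markers of outer radial glia in other species were also lower, 10 of 12 (11 adjusted over the list alone), with MOXD1 (-2.29 ± 0.28), PTN (-2.26 ± 0.30), ITGB5 (-1.98 ± 0.22) and TNC (-1.92 ± 0.23) the largest, while SDC3 was higher. That list had adjusted p = 5.16e-06, and adjusted p = 0.183 with an estimated correlation. HOPX was at -1.36 ± 0.28. Cell cycle genes were lower, with 14 of 15 G2/M genes, such as BUB1 (-1.09 ± 0.16) and CDK1 (-1.05 ± 0.17), and 13 of 18 G1/S genes, such as E2F1 (-1.10 ± 0.21). Adjusted over the list alone, 14 and 17 passed, and camera gave 5.86e-07 and 4.31e-06, with adjusted p = 0.293 and 0.281 with an estimated correlation. Of 13 intermediate progenitor genes 4 were lower, also adjusted over the list alone, and EOMES was at -0.36 ± 0.28 (list adjusted p = 0.161). Whether CP tissue in the OSVZ captures lowered the progenitor and cell cycle genes was not tested.

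Notch genes were lower in OSVZ than in VZ in 12 of 18 cases (14 adjusted over the list alone), such as LFNG (-1.93 ± 0.27) and NOTCH2 (-1.81 ± 0.19), and JAG2 was higher. Matrix and integrin genes were lower in 15 of 25 cases, such as LAMB2 (-2.75 ± 0.36) and COL4A5 (-1.98 ± 0.35), with FBLN1 higher and the same counts adjusted over the list alone. Camera gave adjusted p = 5.04e-05 and 2.56e-06 for these 2 lists, and adjusted p = 0.232 and 0.224 with an estimated correlation. Of 17 interneuron genes 6 were lower, also adjusted over the list alone (adjusted p = 0.0553), and 0 of 10 microglia genes passed (0.544).

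Choroid plexus and cilia genes were lower in OSVZ than in VZ, with uneven levels among the VZ libraries. TTR, the main secreted protein of the choroid plexus, was at 530 in VZ 1, 2517 in VZ 2 and 33.8 in VZ 3, and at 3.18 ± 2.76 in OSVZ. All 4 choroid plexus genes and all 7 cilia genes tested were lower in OSVZ, over all genes and adjusted over the list alone (camera adjusted p = 0.00989 and 3.78e-05; adjusted p = 0.293 and 0.217 with an estimated correlation). The cilia median was -1.43, and -0.88 without VZ 2, where FOXJ1, RSPH1 and SPAG17 fell below the filter. Of the choroid plexus genes, AQP1 lost its call without every library but VZ 3 (adjusted p = 0.108 and 0.143 without VZ 1 and VZ 2, 0.0576, 0.0598 and 0.0606 without ISVZ 1 to 3, 0.116, 0.0711 and 0.0970 without OSVZ 1 to 3, and 0.0599, 0.0599 and 0.0585 without CP 1 to 3). It was also lost with equal totals (0.0525), a pseudocount of 0.1 (0.0549) and no filter (0.167). Astrocyte genes were lower in 6 of 9 cases (9 adjusted over the list alone) and subpallial progenitor genes, such as GSX2 (-1.80 ± 0.31), in 4 of 7 (5 adjusted over the list alone), with adjusted p = 1.48e-04 and 0.0115, and adjusted p = 0.221 and 0.338 with an estimated correlation. Without VZ 2 the contrast called 2579 genes in all, 1064 higher and 1515 lower. Without VZ 1 and VZ 2, the libraries with the highest TTR, it called 1190, 398 higher and 792 lower. Of the 20 genes named by size 7 lost their call in that fit, SYT4 (adjusted p = 0.0798, and 4.93e-04 to 0.0246 in the other alternatives) and TTR (0.270, and 4.77e-04 to 0.0467) among them, and 2 fell below the filter. OLIG1 (0.0511, and 5.88e-04 to 0.00824), PDGFRA (0.0518, and 4.49e-04 to 0.00972) and HOPX (0.0857, and 7.99e-04 to 0.0246) lost theirs there too. With 1 VZ library left in that fit, their log2 differences were 2.10 against 2.47, 1.72 against 1.87 and -1.37 against -1.36, while SYT4 was at 1.38 against 3.32 and TTR at -3.41 against -6.77.

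**Figure D5:**
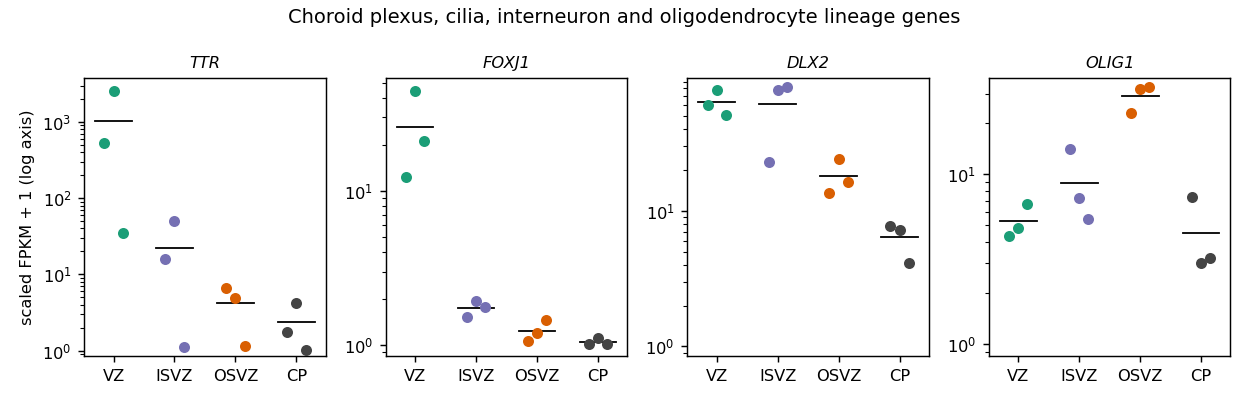
Scaled FPKM plus 1 on a log axis for TTR (choroid plexus), FOXJ1 (motile cilia), DLX2 (interneuron lineage) and OLIG1 (oligodendrocyte lineage), 1 point per library and a line at the mean of each layer. TTR is at 530, 2517 and 33.8 in the VZ libraries, and OLIG1 averages 28.1 in OSVZ.

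ISVZ was compared with VZ, its neighbour on the ventricular side. FOXJ1 was at 0.736 ± 0.205 in ISVZ and 24.9 ± 16.6 in VZ (SD, n = 3), the tetraspanin CD9 (TSDBGID.24086, chromosome 7, 34674240 to 34714728) at 5.26 ± 1.20 against 46.8 ± 24.6, and GJA1 at 14.6 ± 7.47 against 82.4 ± 14.7. PDE10A, a phosphodiesterase (TSDBGID.20210, chromosome 4, 2509907 to 2563724), was higher at 6.90 ± 1.29 against 2.38 ± 1.15. The limma contrast called 1228 genes, 216 higher and 1012 lower in ISVZ, and 24 and 427 of them differed at least 2-fold. The split was 369 higher and 801 lower with quantile normalisation, 137 and 1032 with equal totals, and 173 and 895 with the FPKM as deposited.

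Radial glia genes were lower in ISVZ in 10 of 16 cases (13 adjusted over the list alone), with VIM at log2 -1.64 ± 0.22 and CRB2, an apical polarity gene, at -1.40 ± 0.21 (camera adjusted p = 1.49e-09, adjusted p = 0.183 with an estimated correlation). Outer radial glia genes were lower in 7 of 12 cases (11 adjusted over the list alone), with ITGB5 at -1.70 ± 0.22 and TNC at -1.30 ± 0.23 (3.89e-08, adjusted p = 0.183 with an estimated correlation). Matrix and integrin genes were lower in 13 of 25 cases (16 adjusted over the list alone), such as LAMB2 (-2.27 ± 0.36), and Notch genes in 8 of 18 (12 lower and 1 higher adjusted over the list alone), such as LFNG (-1.65 ± 0.27) and NOTCH2 (-1.28 ± 0.19), with adjusted p = 1.49e-09 and 2.31e-05, and adjusted p = 0.183 and 0.224 with an estimated correlation. Astrocyte genes were lower in 6 of 9 cases (9 adjusted over the list alone), cilia genes in 4 of 7 (7 adjusted over the list alone), such as SPAG17 (-1.28 ± 0.20), and choroid plexus genes in 2 of 4 (4 adjusted over the list alone). Camera gave adjusted p = 9.37e-07, 4.24e-06 and 0.00235 for these 3 lists, and adjusted p = 0.183, 0.183 and 0.232 with an estimated correlation. TTR itself did not pass (-5.23 ± 1.56).

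Of the synapse and axon genes 3 of 21 passed, or 9 adjusted over the list alone, with a median of 0.60 (camera adjusted p = 8.39e-09, adjusted p = 0.221 with an estimated correlation), and of the newborn and migrating neuron genes 2 of 14 passed, or 7 adjusted over the list alone, with a median of 0.64 (3.18e-07, adjusted p = 0.183 with an estimated correlation). Upper-layer (1 of 12 higher), deep-layer (1 of 12 higher) and subplate genes (1 of 8 lower, median 0.05 and mean -0.18) did not pass as lists (adjusted p = 0.131, 0.117 and 0.858), with the same counts adjusted over the list alone. Microglia genes had a median of -0.49 (1 of 10 lower, also adjusted over the list alone), at adjusted p = 0.0114, and adjusted p = 0.377 with an estimated correlation, a call lost without ISVZ 3 (0.177, median -0.26) and without VZ 1 and VZ 2 together (0.252, median -0.29). No intermediate progenitor gene passed (0 of 13; camera adjusted p = 0.672), with a list median of -0.08 where camera's direction was up, and the G2/M list did not pass (0 of 15; adjusted p = 0.0879). The G1/S list passed camera (median -0.30, 0 of 18 members; 0.0180, adjusted p = 0.563 with an estimated correlation), a call lost without VZ 3 (adjusted p = 0.149, median -0.18) and without ISVZ 2 (0.277, median -0.13). The total moved to 394 genes without VZ 2 (30 higher and 364 lower), 589 without VZ 3 (77 and 512), 812 without ISVZ 1 (88 and 724) and 509 without ISVZ 2 (36 and 473), and to 107 without VZ 1 and VZ 2 together (3 and 104). Of the 20 genes named by size 6 kept their call with each library left out, CD9 and PDE10A among them, 11 lost it without at least 1 library, and 3, FOXJ1 among them, fell below the filter when any 1 of the VZ libraries was left out. Without VZ 1 and VZ 2 together 11 of the 20 lost their call, 4 kept it and 5 fell below the filter. The calls of PDE10A (adjusted p = 0.264, and 0.00582 to 0.0488 in the other alternatives), GJA1 (0.0916, and 0.00310 to 0.0193), CRB2 (0.0569, and 0.00310 to 0.0209) and LFNG (0.0529, and 0.00379 to 0.0255) were lost in that fit, which has 1 VZ library left. Their log2 differences there were 0.73 against 1.26, -2.32 against -2.52, -1.56 against -1.40 and -1.91 against -1.65.

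OSVZ was also compared with ISVZ, the pair of subventricular layers. DYNC1I1 was at 17.2 ± 2.86 in OSVZ and 3.57 ± 0.234 in ISVZ (SD, n = 3), a log2 difference of 1.98 ± 0.198 (SE) with adjusted p = 0.00441, and it passed with each of the 12 libraries left out (highest adjusted p = 0.0476). The receptor subunits GABRA5, for GABA, and GLRA2, for glycine, were at 6.04 ± 2.22 against 0.817 ± 0.296 and at 12.1 ± 3.39 against 2.79 ± 0.924. FZD2, a Wnt receptor, was lower at 6.45 ± 0.148 against 13.4 ± 2.99. The limma contrast called 85 genes, 68 higher and 17 lower in OSVZ, and 2822 at an unadjusted p under 0.05. The split was 120 higher and 37 lower with quantile normalisation, 19 and 3 with equal totals, and 40 and 14 with the FPKM as deposited. With a filter of 5 it was 197 and 102, and without OSVZ 3 it was 1 and 2. The call for GABRA5 was lost without ISVZ 2 (adjusted p = 0.0718), ISVZ 3 (0.125), OSVZ 1 (0.0702) and OSVZ 3 (0.0547). Without the same libraries GLRA2 (0.0739, 0.125, 0.0702 and 0.0571) and FZD2 (0.0664, 0.0815, 0.0702 and 0.0699) lost theirs. With no filter the calls of GABRA5 (0.0858), GLRA2 (0.105) and FZD2 (0.0751) were also lost, as were GABRA5 with a pseudocount of 0.1 (0.0523) and FZD2 without VZ 1 and VZ 2 together (0.0587).

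In OSVZ against ISVZ, synapse and axon genes had a median of 0.80 with 4 of 21 members past the test (16 adjusted over the list alone). Subplate genes had a median of 0.93, with 0 of 8 past the test over all genes and 7 higher and 1 lower adjusted over the list alone. Oligodendrocyte precursor genes had a median of 0.84 (0 of 6, or 4 adjusted over the list alone) and microglia genes of 0.56 (1 of 10, or 4 adjusted over the list alone). Camera gave adjusted p = 2.97e-11, 0.00298, 4.17e-04 and 2.44e-04 for these 4 lists, and adjusted p = 0.183, 0.183, 0.224 and 0.239 with an estimated correlation. The call for subplate genes was lost with a filter of 5 (adjusted p = 0.152), and the microglia median was 0.31 without ISVZ 3. G2/M genes had a median of -0.74 (0 of 15, or 14 lower adjusted over the list alone) and G1/S genes of -0.46 (0 of 18, or 8 lower adjusted over the list alone). Their adjusted p was 1.83e-10 and 1.07e-06, and adjusted p = 0.224 and 0.255 with an estimated correlation, and the G1/S median was -0.29 without ISVZ 3.

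Radial glia genes had a median of -0.31 in OSVZ against ISVZ (1 of 16, or 5 adjusted over the list alone). Intermediate progenitor genes had a median of -0.35 (1 of 13, or 4 lower and 1 higher adjusted over the list alone). For interneuron genes the median was -0.79 (0 of 17, or 6 adjusted over the list alone), and for subpallial progenitor genes it was -1.54 (0 of 7, or 3 adjusted over the list alone). Camera called these 4 lists lower at adjusted p = 1.94e-05, 0.00302, 1.94e-05 and 3.43e-04, with adjusted p = 0.232, 0.183, 0.302 and 0.224 with an estimated correlation. The median was -0.60 for radial glia without ISVZ 2, -0.59 for intermediate progenitors without ISVZ 1 and -0.94 for subpallial progenitors without ISVZ 3. As list medians against the mean of the 12 libraries, subpallial genes were at -0.06, 1.12 and 1.72 in ISVZ 1 to 3 and -0.84, -0.09 and -0.28 in OSVZ 1 to 3, and interneuron genes at -0.06, 1.44 and 1.17 in ISVZ 1 to 3 and -0.71, -0.02 and -0.19 in OSVZ 1 to 3. Outer radial glia genes had a median of -0.31 (0 of 12, or 1 lower and 1 higher adjusted over the list alone), at adjusted p = 0.0465, and adjusted p = 0.335 with an estimated correlation. That call was lost without VZ 2 (adjusted p = 0.0501), ISVZ 1 (0.268) and OSVZ 1 (0.236, median -0.16). It was also lost with the FPKM as deposited (0.0552), quantile normalisation (0.0519), a pseudocount of 0.1 (0.0706), a filter of 5 (0.156) and without VZ 1 and VZ 2 together (0.0521).

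The count for OSVZ against ISVZ depended on the libraries used. It was 25, 21 and 46 without VZ 1, VZ 2 and VZ 3, 556, 2 and 2 without ISVZ 1, ISVZ 2 and ISVZ 3, 2, 272 and 3 without OSVZ 1, OSVZ 2 and OSVZ 3, and 40, 28 and 46 without CP 1, CP 2 and CP 3. Of the 20 genes named by size 19 lost their call without at least 1 library, and 16 lost it without VZ 1 and VZ 2 together.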

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

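The fit without VZ 1 and VZ 2 was chosen only after the data were seen; the other alternatives were planned. Among the alternatives run, the calls among the 4 layers, in CP against the germinal layers and for the list tests stayed within 1.5 times their main counts. These list alternatives all kept camera's preset correlation, and 0 of the 92 list tests passed with an estimated one. With each library left out, the counts ranged from 6282 to 7290 among the 4 layers, 6213 to 7500 for CP, 2579 to 3982 for OSVZ against VZ, 394 to 1375 for ISVZ against VZ, 2 to 556 for OSVZ against ISVZ and 48 to 54 for lists, and the exact permutation p of CCNB1IP1 from 0.326 to 0.989. The filters, variance models and block do not enter that permutation test. Without VZ 1 and VZ 2 together, 1190, 107 and 21 genes were called for OSVZ against VZ, ISVZ against VZ and OSVZ against ISVZ, with fewer samples in the fit. ISVZ against VZ gave 787 calls with no filter, 715 with a filter of 5 and 732 with its 6 libraries alone. OSVZ against ISVZ gave 54 with the FPKM as deposited, 22 with equal totals, 157 with quantile normalisation, 19 with a pseudocount of 0.1, 8 with no filter, 299 with a filter of 5 and 4 with its 6 libraries alone; the cause was not tested. Titles of the 4 layers share the replicate numbers 1 to 3, but no label says what these numbers mark. The main fit therefore did not pair the libraries, although the values point towards pairing. Deviations from the layer means correlated above 0.1 in 16 of 18 same-numbered pairs, with a mean r of 0.218 and a lowest r of 0.0628. Every one of the 12 libraries correlated best with its own number, so the main p-values may leave out a pairing. With the replicate block, 206 genes were called for OSVZ against ISVZ, 8083 among the layers, 7987 for CP, 4505 for OSVZ against VZ, 1587 for ISVZ against VZ and 52 lists. Over all alternatives, single named genes kept their side of the threshold in 8729 tests, lost it in 747 and gained it in 90, lists in 1942, 21 and 45, and 0 reversed. FPKM gives no read counts, so precision rests on the deposited bounds, and relative depth differed by up to 2.70 times between libraries.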

Other observations

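The test of cilia genes against TTR was chosen only after the result was seen; the other tests were planned before their results were seen. Genes with their highest level in OSVZ, chosen after their values were seen, included OLIG1, a transcription factor of the oligodendrocyte lineage, at 28.1 ± 5.39 in OSVZ (SD, n = 3), 4.29 ± 1.22 in VZ, 7.93 ± 4.51 in ISVZ and 3.52 ± 2.43 in CP. PDGFRA, a receptor of oligodendrocyte precursors, was at 7.44 ± 1.60, 1.29 ± 0.255, 2.37 ± 0.952 and 1.23 ± 1.15 in the same order. UNC5D, a netrin receptor of multipolar migrating neurons, averaged 27.7 (SD 6.79), 7.76, 21.7 and 4.50. None of these named genes was called higher in OSVZ than in ISVZ. In limma, 848 genes were called higher in VZ than in each other layer, 1566 in CP, 2 in OSVZ (HS6ST2li1 and an open reading frame without a gene symbol) and 0 in ISVZ.

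The list of cortical folding and malformation genes did not pass camera in any contrast. Its camera adjusted p was 0.0737 for CP, 0.460 for OSVZ against VZ, 0.394 for ISVZ against VZ and 0.527 for OSVZ against ISVZ. With fry, which does not compare the list with other genes, the adjusted p was 1.495e-05 for CP and 0.00784 for OSVZ against VZ. Its members went both ways. In CP 10 of 18 were lower, such as the fibroblast growth factor receptors FGFR3 (-2.89 ± 0.28) and FGFR2 (-2.67 ± 0.11), and 4 were higher, TRNP1, FLRT3, DCX and MCPH1, also adjusted over the list alone. FGFR2 was also lower in OSVZ than in VZ (-2.04 ± 0.14) and in ISVZ than in VZ (-1.34 ± 0.14), and ARHGAP11A was lower in CP (-2.14 ± 0.18) but not past the test in OSVZ against VZ (-0.10 ± 0.22).

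Genes of the interneuron lineage varied among the ISVZ libraries. DLX2 was at 22.0, 77.2 and 80.7 and GAD2 at 5.73, 30.6 and 36.5 in ISVZ 1 to 3. NKX2-1, a gene of the medial ganglionic eminence, stayed at or below 0.365 in all 12 libraries. LHX8, another untested gene of the subpallial progenitor list, reached 23.4 in its highest library. The fetal globin gene HBG was at 521 ± 72.4, 489 ± 97.3, 343 ± 55.2 and 129 ± 66.4 in VZ, ISVZ, OSVZ and CP (SD, n = 3). The stress, meninges and endothelial lists did not pass in OSVZ against VZ (adjusted p = 0.774, 0.202 and 0.803). OSVZ 3 stood apart on the Cajal-Retzius list, of which 2 genes were tested, with a median of 2.71 against the mean of the 12 libraries, and -0.27 and 0.16 in OSVZ 1 and OSVZ 2. In CP 2 the Cajal-Retzius median was 1.11, against -0.19 and -0.84 in CP 1 and CP 3. OSVZ 3 was also the highest OSVZ library on the synapse and axon list, at 0.82 against 0.27 and 0.10. Without OSVZ 3 that list had a median of 0.59 in OSVZ minus ISVZ (0.80 with it). Of the lists with too few members to test, RELN and CALB2 of Cajal-Retzius cells did not pass in CP (0.84 ± 0.52 and -0.77 ± 0.64), the erythroid genes AHSP and ALAS2 were lower there (-0.86 ± 0.18 and -0.89 ± 0.19), and mitochondrial transcripts were not found by symbol.

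Of 7 motile cilia genes 4 were lower in ISVZ than in VZ, as were the choroid plexus genes FOLR1 and OTX2, while TTR and AQP1 did not pass, so choroid plexus tissue in the VZ captures is a candidate source of the cilia genes. FOXJ1, RSPH1 and SPAG17 passed without each of the 9 libraries of the other layers, and fell below the filter when any 1 of the VZ libraries was left out. TEKT1 lost its call without VZ 2 (adjusted p = 0.140), VZ 3 (0.117), ISVZ 1 (0.104) and ISVZ 2 (0.114). FOLR1 lost it without VZ 1 (0.0533), ISVZ 1 (0.0886), ISVZ 2 (0.0763), ISVZ 3 (0.0898), OSVZ 2 (0.0503) and CP 2 (0.05004), and was at -1.95 without VZ 2. OTX2 lost it without ISVZ 1 (0.0620) and ISVZ 2 (0.0577), with a pseudocount of 0.1 (0.0510) and without VZ 1 and VZ 2 together (0.0747). With no filter FOLR1 (0.140), OTX2 (0.0764), RSPH1 (0.0509) and TEKT1 (0.123) lost theirs. The cilia median was -0.69 without VZ 2 and -0.78 without VZ 3, over the members left. With log2 of TTR plus 1 as a covariate, the median ISVZ minus VZ difference of the 7 cilia genes was -1.23 against -1.28 without it, 5 of the 7 were past adjusted p 0.05 over the list alone, and FOXJ1 was at -3.41 ± 0.504. This argues against tissue that scales with TTR as the whole source. Of the choroid plexus genes in the same fit, FOLR1 moved from -3.18 to -1.04 and AQP1 from -2.31 to -0.55, but OTX2 only from -2.43 to -2.24 ± 0.775, so choroid plexus tissue that TTR does not track stays open. VZ 2, with the highest TTR (2517), also had the highest FOXJ1 (43.5) and RSPH1 (15.5), while RSPH1 was at 1.85 in VZ 1 with TTR at 530 and at 6.93 in VZ 3 with TTR at 33.8. Cells of the ventricular surface itself that are forming cilia also remain open and were not tested.

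Genes higher in OSVZ than in VZ could come from a mixture of VZ-like tissue and CP tissue in the OSVZ captures. As the source of all these genes the mixture is argued against by 98 genes called higher in OSVZ than in both VZ and CP. They are 5.93% of the 1652 genes higher in OSVZ than in VZ, and for the rest this count does not weigh against a mixture. OLIG1 and PDGFRA are among the 98, as are genes with small differences, such as RPL13 (log2 0.368 over VZ). The 20 simulated mixtures of the VZ and CP means gave at most 12. Those mixtures used a CP share of 46.8% throughout. A mixture of ISVZ-like and CP tissue was not simulated, and only 2 genes were called higher in OSVZ than in each other layer. For the synapse and axon genes the VZ and CP mixture stays open. Of the 21 members 0 were called higher in OSVZ than in CP. This count cannot decide, because 19 of the 21 were called higher in CP than in the germinal layers. Mean levels in VZ, OSVZ and CP were 12.8, 83.6 and 487 for SYT4, but 12.4, 37.1 and 39.1 for SYP. Only SYN2 (0.625, 5.06 and 3.98) and BSN (1.58, 3.52 and 2.37) had a higher mean in OSVZ than in CP. Whether a single share of CP tissue would give the levels of all 21 members was not tested. Sequencing depth as their source is argued against by the fit with log2 relative depth as a covariate, in which 20 of the 21 members were still called (3603 genes in all). Neurons migrating through the OSVZ remain open beside the mixture, as an untested biological source of these genes.

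Other splits of the libraries were tested for each count. Of 100 splits of the 12 libraries into 4 groups of 3, only the real one (1 split) gave as many as 7304 calls. The highest count among the others was 4791. This argues against a random grouping for that count only if the 12 libraries are independent, which the labels do not state. Deviations from the layer means had a mean r of 0.218 between same-numbered libraries and -0.109 between others. The splits ignored these numbers, so they do not settle the question if the libraries are paired. Of 100 splits into 3 and 9, only the real one (1 split) gave as many as 6202 calls in a fit of 2 groups. The highest other count was 1865, and the same limit applies. With 10 splits of 6 libraries the share cannot fall under 0.05. The real count and the highest other were 3937 and 2 for OSVZ against VZ, 1228 and 1 for ISVZ against VZ, and 85 and 5 for OSVZ against ISVZ.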
